A study of Mus musculus with 2 samples.

How the data were processed

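The study profiled acetylation of lysine 27 on histone H3 (H3K27ac), a mark of active promoters and enhancers, in colonic macrophages of mice that lack the transcriptional corepressor Tle4 in myeloid cells (Tle4cKO, a floxed Tle4 gene with Lyz2-Cre) and of mice that carry Lyz2-Cre alone (WT). The assay was CUT&Tag, in which an antibody directs a transposase to the marked chromatin and the tagged fragments are sequenced. Per the labels' protocols, Siglec-F-negative, Ly6C-low, CD64-positive cells of 4 male mice per genotype were sorted at the same time and pooled by genotype, so the series holds 2 libraries, 1 per genotype. The mice were 11.1 weeks old.

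The authors deposited 1 list of peak summits per library. Each summit is a position of 1 bp with a score. Per the submitters' processing notes, the tools were cutadapt 1.14 and Bowtie2 2.2.5 and the genome build was mm10. The peak caller, its settings, any control library and the read depth are not given in the sources used here. The deposited score was read as the −log10 of a p- or q-value per peak, because the list has the layout of a summit file and its lowest scores lie just above 1.30, the −log10 of 0.05. Which of the p- and q-value it is was not stated. Such a score grows with depth and with the share of reads in marked regions. Scores were therefore used to rank or filter summits within one list, apart from a test of whether gene-end and gene-distant summits of like score change alike, and a score is printed as the authors' value for that peak. The depth is unknown, so no interval on the signal at any one peak can be given. A peak without a partner in the other list is a peak that was not called there. It may still carry signal under the calling threshold.

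Summits on chromosomes 1 to 19, X and Y were kept. The 4 WT and 2 Tle4cKO summits on the mitochondrial chromosome were left out of all comparisons. No list of known repeat or high-signal regions was applied, and all other summits were kept as deposited. Positions were counted from 1. Gene positions came from a table of NCBI RefSeq genes on GRCm38.p6, the assembly that mm10 is made from, with 21883 protein-coding genes on these chromosomes. The table gives the outer start and end of each gene but no strand and no exons. The planned promoter window around transcription starts was therefore replaced by a window of 1 kb around either outer end of a protein-coding gene, called a gene end here. A gene end can be the start or the end of transcription, internal promoters are missed, and a summit between a pair of neighbouring genes counts for both. A window of 10 kb around a gene can likewise take in the summit of a neighbour. A gene is said to have both when each list has a summit in its window, at the same place or not. Summits elsewhere inside a protein-coding gene were called gene body and all others intergenic. Moving every WT summit by 20 kb lowered the share at gene ends from 41.6% to 6.55%. The planned motif search needed the genome sequence, which was not used here, and was not run.

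A summit counted as shared when the other list had a summit within 500 bp. The chance level came from 1000 circular shifts of the Tle4cKO summits along each chromosome. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only. With 1 library per genotype there is no test between genotypes, no p-value is given, and no difference has a replicate check. In all, 31 gene lists were fixed before the data were examined. For each list, the share of its genes with a WT summit that also had a Tle4cKO summit was set against 10000 random lists of the same number of genes with WT scores in the same deciles, and is given as a percentile that describes these libraries only. A second percentile sets the share of a list's genes with a WT summit against 10000 random lists matched on deciles of gene length, and was added after the data had been seen. List symbols were matched to the table by symbol or synonym; Mx1, Mx2, Trac and Tpsab1 were not matched. Summits at most 12.5 kb apart were joined into clusters.

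Genes were named by a rule fixed before the data were examined. It takes the Tle family and Lyz2, the 10 genes with the highest score at a gene end in each list, the 10 with the highest score and no summit of the other list at their ends or within 5 kb of that summit, and up to 2 genes per list and class (both libraries, WT only, Tle4cKO only) by score. It also takes the 5 clusters with most summits per library. Not every gene that the rule takes is printed. Alternatives were other windows and distances, score minimums of 5 and 10, WT lists cut to the length of the Tle4cKO list, autosomes only, merged summits and unmatched random lists. The steps were tested on simulated data. Of 2350 simulated summits with a planted partner share of 58.8%, 100% of the planted ones and 0.103% of the others were called shared. Of 50 simulated lists of 40 genes with doubled retention, 50 lay above the 97.5th percentile, and 1 of 50 lists without an effect lay outside the middle 95%. At gene ends the ribosomal protein list held 50 genes with a WT summit and every other list 21 or fewer. The simulation therefore does not show how well short lists or lowered retention would be detected. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.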

Results

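H3K27ac CUT&Tag was carried out on sorted colonic macrophages from WT and Tle4cKO mice, with 1 library of cells pooled from 4 mice for each genotype. The WT list held 10474 summits on the standard chromosomes and the Tle4cKO list 2350, so that 4.46 WT summits were called for each Tle4cKO summit. The median score, the authors' −log10 value per peak, was 4.47 in the WT list and 4.05 in the Tle4cKO list. Read depth was unknown, there was no replicate library of either genotype, and no test between the genotypes was possible.

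The first question was what the profiles showed at the targeted gene. Neither library had a summit in Tle4 (chromosome 19, 14448072 to 14598183, mm10) or within 10 kb of it. Tle4 encodes a Groucho-family corepressor, a protein that represses genes without binding DNA itself. Of the other family members, Tle2, Tle3, Tle5 and Tle6 had no summit within 10 kb in either library. Tle1 had a single WT summit with a score of 3.17 at position 72200702 of chromosome 4, near its outer end, and none in Tle4cKO. Lyz2, the lysozyme gene whose promoter drives the Cre recombinase, also had no summit within 10 kb in either library. The summits therefore give no check of the genotype labels, and acetylation around a gene need not change when its exons are deleted.

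The second question was how far the acetylated regions of the genotypes overlapped. Most regions called in Tle4cKO were also called in WT, while most regions called in WT were not called in Tle4cKO. Of the 2350 Tle4cKO summits, 1874 (79.7%, 95% interval 78.1 to 81.4%) had a WT summit within 500 bp, against a mean of 0.422% and a highest value of 0.936% in 1000 circular shifts. Of the 10474 WT summits, 1883 (18.0%, 95% interval 17.2 to 18.7%) had a Tle4cKO summit within 500 bp. Partner summits lay at a median distance of 91 bp from each WT summit. When the WT list was restricted to its 2350 highest scores, 42.5% of the Tle4cKO summits had a partner in it.

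**Figure D1:**
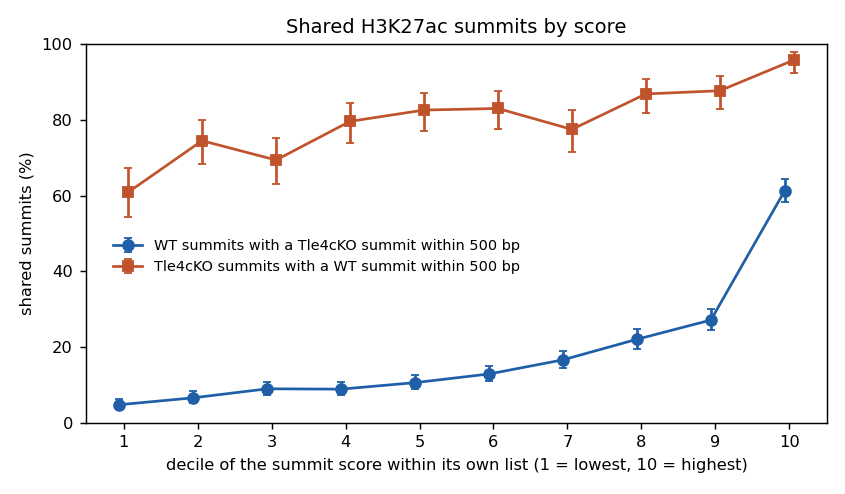
Share of summits (y axis, percent) with a summit of the other library within 500 bp, by decile of the score within each list (x axis, 1 lowest to 10 highest). Points are shares with exact 95% intervals. WT summits are in blue and Tle4cKO summits in orange. The WT share goes from 4.77% in the lowest decile to 61.3% in the highest, and the Tle4cKO share from 60.9% to 95.7%.

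The WT regions that were also called in Tle4cKO were mainly the high-scoring ones. In the lowest decile of WT scores 4.77% (95% interval 3.56 to 6.24%) of 1048 summits were shared, and in the highest decile 61.3% (58.3 to 64.3%) of 1047 were. The share was 27.1% in the decile below it. WT summits with a partner had a median score of 6.55 and those without one 4.21. Among Tle4cKO summits, the 476 without a WT partner had a median score of 3.33, against 4.25 for the shared ones. The shorter list was seen on every autosome: the ratio of WT to Tle4cKO summits ranged from 3.95 on chromosome 13 to 5.25 on chromosome 16. It was 4.25 on the X chromosome. The Y chromosome held 14 WT and 9 Tle4cKO summits.

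With a window of 1 kb, gene ends were the most frequent location in both libraries. In WT, 41.6% (95% interval 40.7 to 42.5%) of summits lay within 1 kb of an outer end of a protein-coding gene, 34.6% lay elsewhere in a gene and 23.8% were intergenic. In Tle4cKO the shares were 48.0% (45.9 to 50%), 30.0% and 22%. With a window of 500 bp the WT share at gene ends was 34.5%, so they were no longer ahead of gene bodies. WT summits at gene ends were shared in 22.6% (21.3 to 23.8%) of cases, those in gene bodies in 14.4% (13.2 to 15.5%) and intergenic ones in 15.2% (13.8 to 16.7%). Their median WT scores were 5.07, 4.09 and 4.19. The 476 summits called in Tle4cKO alone lay at gene ends in 30.0% (25.95 to 34.4%) of cases, in gene bodies in 39.5% and between genes in 30.5%. The higher Tle4cKO share at gene ends did not hold at score minimums or with the WT list cut to the length of the Tle4cKO list. Among summits scoring at least 5, 52.7% of those in WT and 47.1% of those in Tle4cKO lay at gene ends. At a score of at least 10, which kept 603 WT and 156 Tle4cKO summits, the shares were 59.7% and 16.0%. Of the 200 highest summits of each list, 41.0% and 23.5% lay at gene ends. Of the 2350 highest WT summits, 57.7% lay at gene ends. Of the 50 highest summits, 37 in each list lay over 5 kb from any protein-coding gene, and no list of known high-signal repeat regions was applied.

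**Figure D2:**
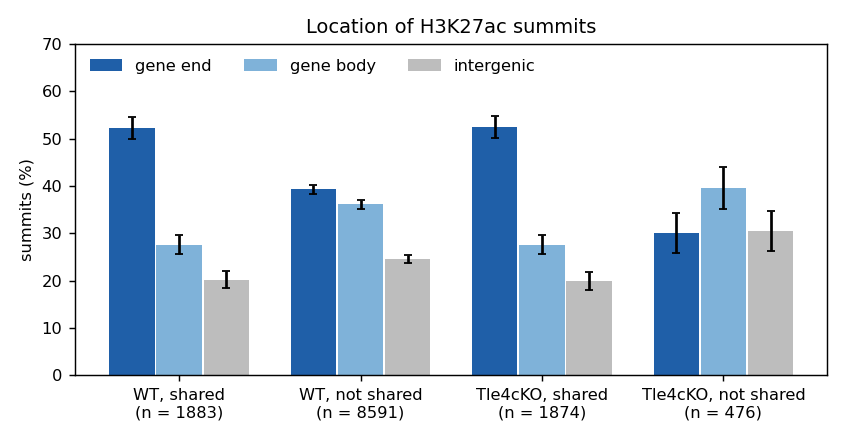
Share of summits (y axis, percent) at gene ends, in gene bodies and between genes, for summits with and without a partner in the other library within 500 bp. Bars are shares with exact 95% intervals, and n is the number of summits. Shared summits lie at gene ends in 52.2% (WT) and 52.5% (Tle4cKO) of cases, and unshared ones in 39.3% and 30.0%.

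At the level of genes, 4950 of 21883 protein-coding genes (22.6%) had a gene-end summit in WT and 1355 (6.19%) in Tle4cKO. Both libraries marked 1225 genes, where independent lists of these sizes would share 307. A WT summit alone was found at 3725 genes and a Tle4cKO summit alone at 130. The 10 genes with the highest WT scores at a gene end all had a Tle4cKO summit there as well. They included Lrpprc, which encodes a regulator of mitochondrial RNA, with a WT score of 28.8 and a Tle4cKO score of 18.0. Cops5, a subunit of the COP9 signalosome, shared its summit with the neighbouring Cspp1, with scores of 24.8 and 16.9. The summit shared by Ddx54, an RNA helicase, and Rita1 had scores of 28.5 and 16.7. Bccip (28.6 and 12.0), Rab28 (26.4 and 8.06) and Zfp433 (22.9 and 9.81) were also among these 10 genes. Wls (78.2 and 65.4) and Gm32584 (54.8 and 56.4) had the highest scores in both lists. Aldh4a1, Atg101 and Sem1 were among the 10 highest genes of the Tle4cKO list but not of the WT list, with Tle4cKO scores of 14.7, 14.5 and 12.6 and WT scores of 21.1, 13.3 and 13.5.

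The 10 genes with the highest-scoring WT gene-end summits and no Tle4cKO summit within 5 kb had WT scores from 14.2 to 20.2. Gosr1, a Golgi SNARE, had the highest of these scores at position 76763354 of chromosome 11. A summit with a score of 15.9 lay where the ends of 2 genes overlap, Copa, a coat protein of Golgi vesicles, and Ncstn, a subunit of gamma-secretase, the protease that cleaves Notch. Use1, an endoplasmic reticulum SNARE, had a score of 15.2. Nhej1, a factor of non-homologous end joining, shared a summit of 16.7 with Slc23a3, and Fen1, the flap endonuclease, had the lowest of these scores. Calm3, a calmodulin gene, scored 15.6, Siah1b, a ubiquitin ligase, 15.4, and 0610009B22Rik 18.1. The opposite class was ranked within the Tle4cKO list. Nt5dc1 (9.31), the splicing factor gene Hnrnpr (8.42), the mitochondrial leucyl-tRNA synthetase gene Lars2 (7.04), Bud23 and Dnajc30 (a common summit of 6.46) and the nucleoporin gene Nup54 (6.04) had a Tle4cKO summit at a gene end and no WT summit within 10 kb of the gene. Resf1, Hyou1, Pnp and Dbr1 had Tle4cKO gene-end scores of 6.71, 6.49, 6.47 and 6.21, and each had a WT summit elsewhere within 10 kb of the gene.

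The third question was which groups of macrophage genes were marked and which of them were called in both genotypes. The NF-kB pathway was the most widely marked of the 30 lists with under 100 genes. Of its 33 genes, 28 had a WT summit in the gene or within 10 kb, 10 of these also had a Tle4cKO summit, and none had a Tle4cKO summit alone. Over all protein-coding genes, 39.2% had a WT summit in this window and 27.6% of these also had a Tle4cKO summit. A gene with both need not have them at the same place: 89.8% of the 2366 genes with both had a WT and a Tle4cKO summit within 500 bp of each other. Relb, a subunit of NF-kB (7.23 in WT and 5.43 in Tle4cKO), and Ikbkg, the regulatory subunit of the IkB kinase (8.31 and 3.99), had gene-end summits in both. Nfkbib, an inhibitor of NF-kB (13.9), and Irak4, a kinase of Toll-like receptor signalling (12.0), had them in WT alone. Of the 31 inflammatory cytokine and chemokine genes, 13 had a WT summit within 10 kb with no Tle4cKO summit and 2 had both. Tnf had both at the same place (5.40 and 3.26), the Il27 summits lay 9365 bp apart, and Il23a (7.09) and Il1a (7.08) had WT summits alone. The summits of Tnf, Il23a and Il1a lay outside these genes and not at their ends, so they may belong to neighbours.

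Genes of antigen presentation, lysosomes and lipid handling were also widely marked. Cd74, the invariant chain of MHC class II, had gene-end summits in both libraries (8.90 and 7.27), as did the class II gene H2-Eb1 (4.57 and 1.92). Of the 15 genes in the MHC class II list, 9 had a WT summit alone within 10 kb, among them Cd40 (7.56) and H2-Oa (7.23), and 2 had both. Ciita, the class II transactivator, had a Tle4cKO summit alone (2.31). The H2-Oa and Ciita summits lay outside these genes and not at their ends. Of 30 lysosome genes, 18 had a WT summit alone and 5 had both; the protease gene Ctsb had both (9.83 and 3.42) and the lipase gene Lipa a WT summit alone (10.4). Of 26 genes of lipid handling and nuclear receptors, 11 had a WT summit alone and 8 had both, including the nuclear receptor gene Pparg (9.41 and 6.88). Of 80 ribosomal protein genes, 44 had a WT summit alone and 18 had both, with Rps23 at 18.9 and 11.7 and Rps15 in WT alone at 9.19.

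Marker genes of the macrophage lineage itself did not stand out from random genes at their ends. At gene ends, 6 of 30 macrophage identity genes (20%, 95% interval 7.71 to 38.6%) had a WT summit, a share within that of random lists of like gene length (40.3th percentile). Only Csf2ra, a receptor chain for GM-CSF, had one in both libraries (7.51 and 5.24). Cd14, the co-receptor for lipopolysaccharide (5.73), and Fcgr1, which encodes the CD64 antigen used in the sort (5.49), had one in WT alone. Within 10 kb, 13 of the 30 had a WT summit alone, 1 had both and Ptprc had a Tle4cKO summit alone (4.45). Among 30 genes of resident gut macrophages, 10 had a WT summit alone within 10 kb and 4 had both. Nr4a1 (13.3 and 14.5) and the TGF-beta receptor gene Tgfbr2 (6.52 and 2.59) had both. The Nr4a1 values are those of the gene-end summits of its neighbour Atg101, and Nr4a1 had no summit at its own ends. Selenop (9.83) and the Notch regulator Dtx4 (6.62) had a WT summit alone. Of the 15 monocyte genes, 2 had a WT summit alone and 1, F13a1, a Tle4cKO summit alone (7.17). Of the 19 M2-associated genes, 9 had a WT summit alone and 0 had both. Random lists of like WT score retained a median of 22.2%, and the list lay at their 6.33th percentile, inside the middle 95%. At gene ends it lay at the 35.5th percentile.

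Markers of other cell types that a colon preparation can hold were measured in the same way. No epithelial (30 genes), fibroblast and muscle (20), neutrophil (20) or T cell (19) marker had a gene-end summit in either library. Within 10 kb, WT summits lay at 2 of 30 epithelial, 1 of 20 neutrophil, 5 of 20 endothelial, 4 of 20 fibroblast and muscle, 5 of 19 T cell, 7 of 20 B and plasma cell, 2 of 15 NK and innate lymphoid, 3 of 15 eosinophil, 2 of 14 mast cell and 2 of 15 enteric glia and neuron genes. Among dendritic cell genes, 14 of 18 had a WT summit within 10 kb, 3 of them also in Tle4cKO, including shared summits at Tcf4 (9.54 and 3.42) and Xcr1 (3.58 and 4.06). At gene ends 3 of the 18 (16.7%) had a WT summit, at the 21.5th percentile of random lists of like gene length. As a negative control, 14 of 1109 olfactory receptor genes had a WT summit within 10 kb and 2 had one at a gene end.

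**Figure D3:**
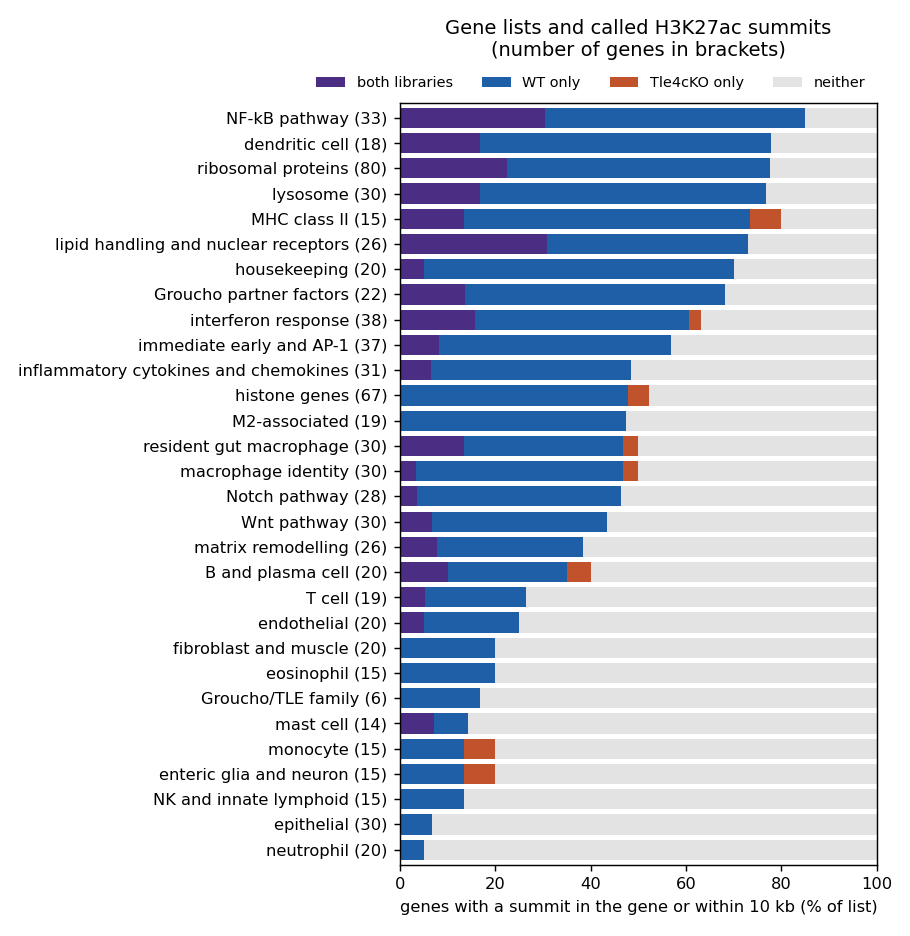
Share of the genes in each list (x axis, percent) that have a called summit in the gene or within 10 kb in both libraries, in WT alone, in Tle4cKO alone or in neither. The number of genes is in brackets, and lists (y axis) are ordered by their WT share. The NF-kB list reaches 84.8% in WT and the neutrophil list 5.00%.

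Groucho partner factors and the Notch and Wnt pathways were examined because Groucho proteins are known to bind transcription factors of these pathways. Immediate early and AP-1, matrix remodelling and interferon response genes are given beside them. Of 22 partner factors, 12 had a WT summit alone within 10 kb and 3 had both. Hdac2, a histone deacetylase, had gene-end summits of 20.3 in WT and 8.51 in Tle4cKO, and Rela had a WT summit alone (7.48). Of 28 Notch pathway genes, 12 had a WT summit alone and 1, the coactivator gene Maml1, had both (8.62 and 3.09). Of 30 Wnt pathway genes, 11 had a WT summit alone, including the kinase gene Gsk3b (12.6), and 2 had both, Dvl3 and Znrf3, whose closest WT and Tle4cKO summits lay 779 and 139865 bp apart and so were not shared. Of 37 immediate early and AP-1 genes, 13 had a gene-end summit in WT, among them Atf4 (7.53) and Batf (7.52), and 0 of these had one in Tle4cKO. The matched random lists retained a median of 15.4%, and the list lay at their 3.06th percentile. Within 10 kb, 3 of 21 were called in both (15.4th percentile). Of 26 matrix remodelling genes, 8 had a WT summit alone within 10 kb, with Adam17 at 10.4, and 2 had both, Mmp19 (4.32 and 5.20) and Adam19 (3.43 and 4.31). The Mmp19 summits lay outside the gene and not at its ends. Of 38 interferon response genes, 17 had a WT summit alone within 10 kb and 6 had both, and Gbp5 had a Tle4cKO summit alone (5.35).

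The share of each list's WT genes that was also called in Tle4cKO was set against genes of like WT score. A list with few WT genes cannot fall below the middle 95% of random lists (the Groucho/TLE family, with 0 of 1 retained, lay at the 44.6th percentile), so a place inside it says little, and with 31 lists examined a place outside can arise by chance. The histone genes lay outside at gene ends (0 of 15, 2.37th percentile) and within 10 kb (0 of 32, 0.015th), but they lie in clusters, and counted as the 13 distinct WT summits behind these 32 genes, 10 on chromosome 13 and 3 on chromosome 3, 16.1% of random draws of summits of like score retained as few. H1f3, H3c6 and H4c6 had a Tle4cKO summit alone within 10 kb (2.45). The housekeeping genes lay outside within 10 kb (1 of 14, 2.37th percentile) but not at gene ends (1 of 9, 23.6th). Of them, Sdha had both and Cltc (8.16) and Tbp (8.35) a WT summit alone. With a window of 50 kb the histone genes moved to the 100th percentile and the housekeeping genes to the 39.6th.

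Runs of neighbouring summits were examined last. Of 8931 WT clusters, 197 (2.21%) held 3 or more summits, and of 2251 Tle4cKO clusters 8 (0.355%) did. The cluster with most summits, 12 in each library, lay at the start of chromosome 9 (3000322 to 3038020 in WT) and overlapped no protein-coding gene; whether it lies in repeats was not tested. The second, at 47745227 to 47788663 of chromosome 6, held 11 WT summits and also overlapped none; the Tle4cKO cluster there (47745222 to 47778297) held 6. Clusters of 8 WT summits lay over a run of genes on chromosome 4 that includes Ifnz, an interferon gene (88773713 to 88805623), over Mid1 on the X chromosome and over Gm52481 on the Y chromosome. Within their bounds lay 1, 1 and 4 Tle4cKO summits. The remaining Tle4cKO clusters among the first 5 held 4 summits on chromosome 10, 3 on chromosome 1 and 3 at Sfi1 on chromosome 11.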

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

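Summits were called on the mitochondrial chromosome, which no comparison uses and where no histones are packed: 4 in WT and 2 in Tle4cKO. The WT count was flagged because it lies above 3, the limit used for flagging. These counts do not show a difference between the libraries. No biological explanation was tested.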

How the results depend on the processing

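The excess of WT over Tle4cKO summits held at every score minimum tried (main 10474 and 2350): 4205 and 746 at a score of at least 5, and 603 and 156 at a score of at least 10. As scores grow with depth, a lower depth alone would also leave this excess. Merging summits within 1 kb left both counts within 1.5 times. The share of Tle4cKO summits with a WT partner (79.7%) was 59.5%, 83.4% and 84.3% at distances of 200, 1000 and 2000 bp, 76.4% and 82.1% at the same score minimums, and 42.5% with only the 2350 highest WT summits. The share of WT summits with a Tle4cKO partner (18.0%) was 13.4%, 19.2%, 19.7%, 13.6%, 21.2% and 42.5% in the same order. Autosomes alone changed neither share beyond its interval, and a distance of 1000 bp did not do so for the lowest or highest decile of WT scores. The WT share at gene ends (41.6%) was 34.5% and 46.6% in windows of 500 and 2000 bp, 52.7% and 59.7% at scores of at least 5 and 10, and 57.7% for the 2350 highest WT summits. The Tle4cKO share (48.0%) was 40.3% and 52.6% in these windows and 47.1% and 16.0% at the score minimums, so the order of the libraries turned at both minimums and with the WT list cut to the length of the Tle4cKO list. Leaving out the highest-scoring summits far from genes, chosen after the data were seen, moved no share at gene ends or between lists beyond its interval. Genes with a gene-end summit numbered 2643, 432 and 366 (WT, Tle4cKO, both) at a score of at least 5, and 446, 27 and 23 at a score of at least 10; the windows left each within 1.5 times. Clusters of 3 or more summits numbered 29 in WT and 5 in Tle4cKO with gaps up to 5 kb, and 603 and 18 with gaps up to 25 kb. At gene ends the number of lists outside the middle 95% went from 1 to 2 both with a window of 2000 bp and with unmatched random lists, which added the immediate early and AP-1 genes (1.75th and 1.25th percentiles). Near genes, a window of 50 kb moved the histone genes from the 0.015th to the 100th percentile and the housekeeping genes to the 39.6th, and brought the Wnt pathway to the 1.81th. The other list percentiles stayed on their side of these limits in 80 alternatives. No replicate could be left out, the motif search was not run, and no paired analysis was possible because each genotype has 1 library. The unknown depth limits every statement about summits that were not called.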

Other observations

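The tests in this part were chosen after the data had been seen, except the comparison of how many gene-end and gene-distant summits were retained and both tests on the histone genes, whose outcomes were set down before their results were computed.

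Against random lists of like gene length, 6 of the 31 lists lay above the middle 95% in their share of genes with a WT summit at gene ends and 7 below, and within 10 kb 11 lay above and 8 below. At gene ends, 63.6% of NF-kB pathway genes, 62.5% of ribosomal protein genes and 53.3% of lysosome genes had a WT summit, where random lists had medians of 27.3%, 16.2% and 26.7%. Histone genes (22.4% against 5.97%), immediate early and AP-1 genes (98.2th percentile) and housekeeping genes (98.4th) also lay above, and these 6 lay above within 10 kb too. The histone share is close to the 22.6% of all protein-coding genes, and clustered histone genes such as H2ac19 and H3c15 count the same summit. Within 10 kb, MHC class II genes (73.3% against 40%), interferon response genes (60.5% against 39.5%) and dendritic cell genes (77.8% against 44.4%) also lay above the middle 95% of random lists, whereas at gene ends they lay within it (61.8th, 82.2th and 21.5th percentiles). The same holds for Groucho partner factors and for lipid handling and nuclear receptor genes. Epithelial (6.67% against 40%), neutrophil (5.00% against 35%) and monocyte genes (13.3% against 40%) lay below it, as did NK and innate lymphoid, mast cell, fibroblast and muscle, enteric glia and neuron and olfactory receptor genes. At gene ends the monocyte list lay within it (8.24th percentile), as did the NK (19.3th), mast cell (22.4th) and glia lists (5.03th). Of the 18 dendritic cell genes, 4 are also members of another list (Batf3, Ccr7, Irf4 and Kit).

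The Tle4cKO list is 4.46 times shorter than the WT list. The retention test did not exclude a lower depth or sensitivity that acts on all regions alike. Below a WT score of 20, retention was compared at like scores, within 20 score bins, and weighted over them. Gene-end summits were then retained in 17.9% of cases and summits over 5 kb from genes in 15.4%. The weighted difference was 2.52 percentage points (95% interval 0.764 to 4.33), within the margin of 5 set beforehand. Without weighting and at all scores, 22.6% of gene-end and 15.2% of intergenic WT summits were shared. Other values bear on an effect on all regions alike but do not settle it. Score ratios were set to 0 where the other list had no summit within 500 bp, so they mix measured ratios with peaks not called. Each ratio below is a median weighted over 3 score ranges. Among WT summits scoring 10 to 30, the median ratio of Tle4cKO to WT score was 0.321 at 357 gene-end summits. It was 0.513 at 71 summits over 5 kb from genes, a difference of −0.191 whose interval holds 0 (−0.337 to 0.0226). For Tle4cKO summits in that range, 23 at gene ends and 37 far from genes, the ratio of WT to Tle4cKO score was higher at gene ends by 0.351 (0.0688 to 0.627). Of the 200 highest summits of each list, 41.0% (95% interval 34.1 to 48.2%) in WT and 23.5% (17.8 to 30.0%) in Tle4cKO lay at gene ends. Of the 100 highest, 24% and 8% did, and of the 50 highest 6% and 4%. A common score minimum of 10 gave 59.7% and 16.0%, but it kept 603 WT and 156 Tle4cKO summits. A single factor would itself lower the second of these shares, so they do not bear on it. The 6 highest summits lay at the same places in both lists, with scores of 127 to 294 in WT and 125 to 304 in Tle4cKO. Some of them were higher and some lower in Tle4cKO, and no repeat regions were filtered out. An exact single factor on all scores would keep the order of summits and so would not give different shares among the 200 highest. Lower depth also adds counting noise, which can reorder summits. Unfiltered summits over 5 kb from genes made up 64 of the 200 in WT and 84 in Tle4cKO. Whether lower depth could give these shares was not tested. As the first of the ratio intervals holds 0, the ratio test did not exclude a single factor either. The calling threshold may account for many of the summits seen in Tle4cKO alone, since 65.5% of these 476 scored below the median of their list. Loss of H3K27ac with the genotype cannot be told apart from a library with a smaller share of reads in marked regions, because there is 1 library per genotype.

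Macrophage identity genes had a gene-end summit in WT no more often than random genes of like length (6 of 30 or 20%, random median 23.3%), although the cells were sorted as macrophages. A gene without a called summit may still carry the mark. Of 20 housekeeping genes 9 had a WT gene-end summit, while Actb and Gapdh, like Lyz2, had no summit within 10 kb. Cells of other types in the sort were tested only as a pool. Of 201 pooled markers of 11 other cell types, 5.47% (95% interval 2.76 to 9.58%) had a WT gene-end summit, below the macrophage share of 20%. All these types together are therefore not supported as the reason. The test cannot exclude a single type, because lists without a gene-end summit, such as the 30 epithelial genes, lower the pooled share. The interval of the macrophage share (7.71 to 38.6%) overlaps that of the pooled markers. Dendritic cells taken alone stay open, although the CD64 gate is meant to remove them: within 10 kb 77.8% of their list had a WT summit against 46.7% of the macrophage identity list, and at gene ends their share of 16.7% (3.58 to 41.4%) is not apart from the macrophage share.

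None of the 32 histone genes within 10 kb of a WT summit had a Tle4cKO summit there, while 3 others had a Tle4cKO summit alone, and with a window of 50 kb the list moved to the 100th percentile. Counted as distinct summits, 0 of 13 were retained, where random summits of like score kept a median of 2, and 16.1% of 10000 draws kept as few, so the pattern may come from a few summits counted for many clustered genes. Fewer cycling cells in the Tle4cKO sample stays open: 5 of 27 proliferation genes with a WT summit were retained, at the 23.8th percentile, between the limits set beforehand, and at gene ends 4 of 17 were retained, at the 54.5th percentile, which goes against it.

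The highest scores of both lists lay far from genes and at the same places. Of the 20 highest summits, 16 in WT and 17 in Tle4cKO were over 5 kb from any protein-coding gene, and all 20 of each were shared. The highest was at position 35305399 of chromosome 9 in WT and at 35305398 in Tle4cKO, with scores of 294 and 304. No list of known high-signal repeat regions was applied, and whether these summits lie in repeats was not tested.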
